A study of Mus musculus with 6 samples.

How the data were processed

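RNA was measured in whole brains of 2-month-old mice on the FVB background, a common inbred strain. Per the labels, 3 samples carried a homozygous knockout of L2hgdh and 3 were wild type. The labels' protocols state that brains were frozen on dry ice, that RNA was taken up in Trizol and that libraries were made from 1 ug of total RNA with an Illumina TruSeq RNA kit. The labels do not say that each library came from a separate animal, so p-values measure the spread between these samples, which may in part be technical.

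The authors deposited 1 table per sample, with an Ensembl gene identifier, a symbol, a locus and 1 value for each of 17978 genes. Per the file headers the value is in FPKM (fragments per kilobase of transcript, scaled to library size, with the header spelled PFKM), already normalized by the authors for length and library size. Per the submitters' processing notes the tools were Trimmomatic, TopHat2 and Cufflinks, with no versions, and the build was hg19, a human build. The identifiers are those of mouse genes: 17775 of them were found in GENCODE M21 for the mouse build GRCm38, 203 were not, and 99.9% of the matched genes lay at an overlapping locus. Coordinates are given as in the files, with 1 added to the start, on the mouse build they match, GRCm38. How the authors chose and ordered the rows is not given in the sources used here. No row was at 0 in all 6 samples, and the row with the lowest maximum reached 0.106 FPKM. Whether reads were counted by strand, and whether a scaling between libraries was applied, is likewise not given.

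The files hold no counts. Depth was estimated from the low values of 1651 genes that have 1 annotated transcript of over 1500 nt, as the factor that turns FPKM into whole fragments with an effective length 200 nt below the annotated length. Between 86.0% and 90.0% of the low values used came within 0.1 of a whole fragment. The estimates ran from 24.2 to 26.0 M (mega) fragments per library. At such a depth 1 FPKM on an effective length of 1 kb stands for about 24.2 to 26.0 fragments. No count test was run, since these fragments are estimates from FPKM.

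A spreadsheet had turned 25 symbols into dates, and these were restored from the gene identifiers. Rows that share a symbol (26 symbols on 52 rows) were summed, which left 17952 symbols. Genes of short RNAs, picked by the start of their symbol, were left out because an abundance per kilobase of so short a transcript is unreliable. The 13381 other genes with a mean of at least 1 FPKM over the 6 samples were tested with limma 3.58.1 in R 4.3.3 (a linear model per gene with empirical Bayes moderation and a mean-dependent prior) on log2(FPKM + 1), with genotype as the only term and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes are on that scale, which understates the change of low genes. L2hgdh was also compared by an exact two-sided permutation test, whose smallest possible p with 3 samples against 3 is 0.1.

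Lists of marker and pathway genes (45 lists, 958 genes, 744 of them tested) were written before the data were examined, as were the test, the rule for naming genes and all alternatives except 1. The 42 lists with at least 5 tested members were tested with camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01, and again with the correlation estimated for each list. No list passed with an estimated correlation. The loss is not explained by correlated members alone. The lists of ATF4 targets and of the HIF response had estimated correlations of 0.00512 and -0.026, below the preset 0.01. Their camera adjusted p still rose from 0.00178 to 0.403 and from 0.0126 to 0.428. The values with an estimated correlation therefore cannot show that correlation between members produced the calls. The fry test, which asks whether a list's genes move one way or, in its mixed form, move at all, was run beside it. Both come with limma, and all p-values over lists were adjusted by Benjamini-Hochberg. The lists too small to test were pituitary with 1 tested member, midbrain and hindbrain with 3 and sex-linked genes with 4.

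Genes are named by a fixed rule: L2hgdh; up to 15 genes in each direction with the largest fold change among those that passed and whose groups did not overlap, leaving out predicted genes and clone names; where fewer than 10 passed in a direction, those with the smallest p to make 10; up to 4 members of each list with the smallest p; and D2hgdh, Idh1, Idh2, Gfap, Mbp, Plp1, Aif1 and Dcx whatever their value. In the upward direction 8 passed, so 2 that did not pass were added, and 14 were named downward. Other genes named were chosen after their values were seen.

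The procedure was tested on 10 simulated data sets of 13381 genes drawn from the means and spread of these samples, with 200 genes changed in each. It recovered 23.4% of genes changed 1.25-fold, 59.8% at 1.5-fold, 79.4% at 2-fold and 95.2% at 4-fold, and 3.45% of calls were false. A list raised by 0.2 log2 was called in 10 of 10 data sets, and 1 unchanged list was called over all of them. The genes were simulated independently of each other, so this does not measure how often lists of correlated genes are called without cause. The alternatives covered other pseudocounts, filters, scalings, sample weights, a replicate block, the prior, the handling of shared symbols and short RNAs, and each sample left out in turn. The 1 alternative added after seeing the data left out the library numbered 1 in both groups, which were rich in transcripts of the choroid plexus. A list of liver transcripts was also written after the values were seen and is used only to describe the libraries. Figures were drawn with matplotlib 3.10.9.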

Results

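Gene expression was compared between 3 whole-brain samples of L2hgdh knockout mice and 3 of wild type mice, all 2 months old. L2hgdh encodes the mitochondrial enzyme that oxidises L-2-hydroxyglutarate to 2-oxoglutarate, and its inherited loss in humans causes L-2-hydroxyglutaric aciduria, a neurometabolic disease. The comparison asks which brain transcripts differ when the enzyme's gene is disrupted. Each library held an estimated 24.2 to 26.0 M (mega) fragments, and values are FPKM as the authors deposited them. Correlation of log2(FPKM + 1) between libraries ran from 0.975 to 0.990. Xist, the transcript of the inactive X chromosome, lay between 75.8 and 94.8 FPKM in all 6 libraries.

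L2hgdh (ENSMUSG00000020988, chromosome 12, 69690436 to 69724874 on GRCm38, minus strand) was lower in all 3 knockout libraries. Its level was 2.49, 2.11 and 1.95 FPKM in the knockout and 5.01, 5.37 and 4.61 FPKM in the wild type. The knockout mean of 2.19 ± 0.278 FPKM (SD, n = 3) was 43.8% of the wild type mean of 4.99 ± 0.381 FPKM (SD, n = 3). The log2 fold change was -0.91 (SE 0.09), with an adjusted p of 0.0233 (limma). The exact two-sided permutation p was 0.1, the smallest that 3 against 3 samples allow. The value is for the whole gene, and which exons the allele lacks is not given in the sources used here, so the remaining signal is not assigned to any part of the transcript. The limma call was lost without knockout replicate 2 (adjusted p = 0.140), knockout replicate 3 (0.133), wild type replicate 2 (0.149) or wild type replicate 3 (0.0883). It was also lost with both libraries numbered 1 left out (0.0540) and with a replicate block (0.0563). Over 17 alternatives the adjusted p ranged from 0.00586 to 0.149 and the log2 fold change from -1.19 to -0.86.

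Beyond L2hgdh, the knockout brains had less mRNA of the metallothioneins Mt1 and Mt2, of the calcium-binding glial protein S100b and of the lipid desaturase Scd1, and more of the astrocyte filament gene Gfap and of Sos2, the gene next to L2hgdh. In all, 24 of 13381 genes passed the threshold, 9 higher and 15 lower in the knockout (limma, Benjamini-Hochberg). Of the 24, 7 changed at least 2-fold on the log2(FPKM + 1) scale, which understates the change of low genes. L2hgdh, at 43.8% of the wild type mean FPKM, is not among these 7. At an unadjusted p under 0.05 there were 1149 genes, 757 higher and 392 lower, where chance gives about 669. The median log2 fold change of all tested genes was 0.0146, and -0.00393 with median-of-ratios rescaling. List medians and counts of higher members below are taken against 0, so part of the smallest list medians is shared by all genes. The groups did not overlap for 14.7% of genes, against 10% by chance. The number of genes fell to 5 without knockout replicate 2, 6 without knockout replicate 3, 3 without wild type replicate 2, 6 without wild type replicate 3 and 13 with both libraries numbered 1 left out, of which 8 were among the 24. Sample weights gave 67 genes, 39 higher and 28 lower, and a prior that does not depend on the mean gave 13, 2 higher and 11 lower. A replicate block gave 5 genes, of which 4 were among the 24 (Mt2, S100b, Gm21984 and Gm21961). All other calls of the 24 were lost with the block, which is not repeated for each gene below. The number of higher genes was 16 without knockout replicate 1 and 19 without wild type replicate 1. Rescaling by median-of-ratios factors or by quantiles gave 5 higher and 15 lower in place of 9 and 15. Of 42 gene lists tested, 17 passed by camera with a preset correlation, 14 higher and 3 lower, but 0 with an estimated correlation and 0 by the directional fry test. The lowest adjusted p by directional fry was 0.0563, for the lists of microglia, ATF4 targets and the HIF response. By the mixed fry test, which ignores direction, 11 lists passed, not all of them among the 17. Without wild type replicate 3 the 17 became 8. The same camera test also passed 4 to 18 lists, with a median of 12, in the 9 splits of the 6 samples that mix the genotypes. Each mixed split still has more samples of one genotype on each side, so it keeps part of any genotype difference. It therefore does not show how often lists pass without one. A list call here does not by itself set the genotypes apart.

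**Figure D1:**
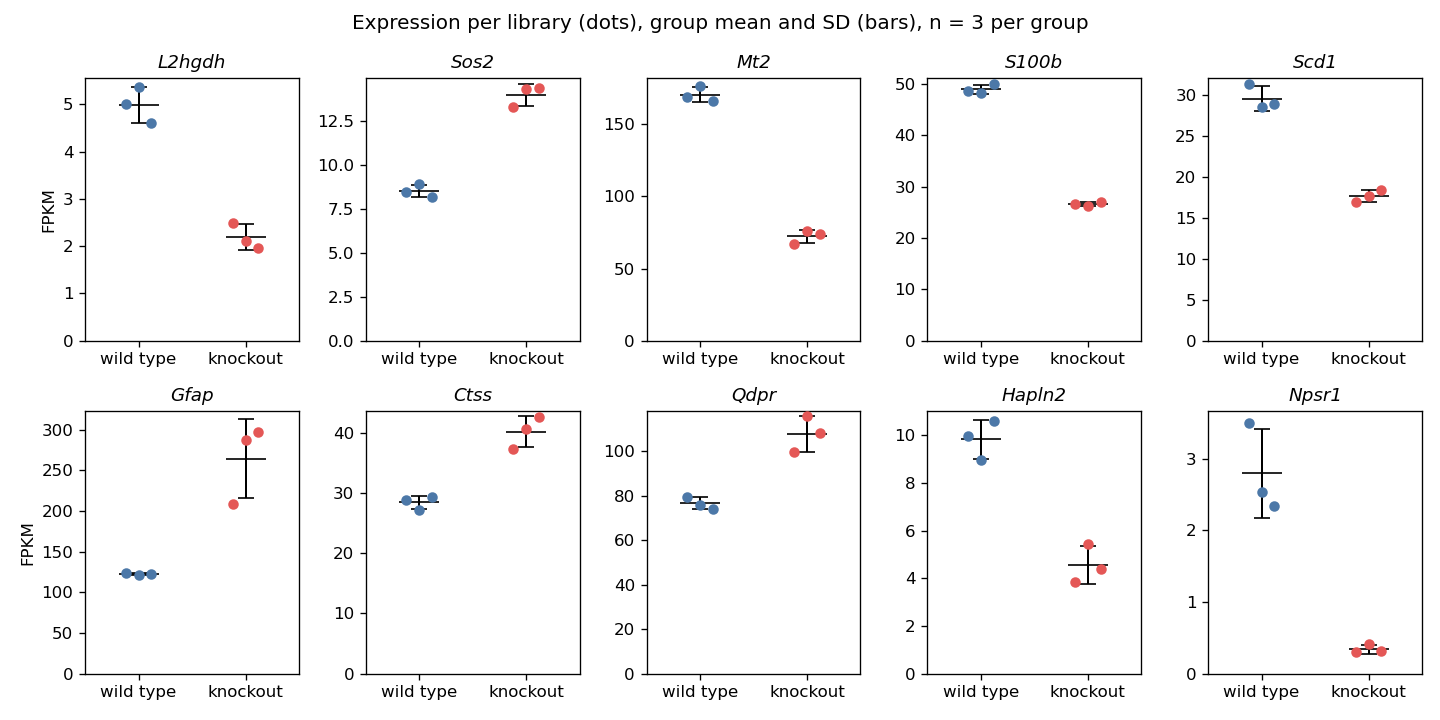
FPKM of 10 genes in each library (dots), with the group mean and SD (bars, n = 3 per group), wild type at left and knockout at right; each vertical axis starts at 0 and has its own scale. In each of the 10 genes the 3 knockout values lie on one side of the 3 wild type values, as for S100b at 26.6 ± 0.429 FPKM in the knockout and 49.0 ± 0.830 FPKM in the wild type.

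The metallothioneins, small proteins that bind zinc and copper, were among the genes with the smallest p. Mt2 (ENSMUSG00000031762, chromosome 8, 94172618 to 94173567) fell from 171 ± 5.25 to 72.3 ± 4.53 FPKM (SD, n = 3 each), a log2 fold change of -1.23 (SE 0.06) with adjusted p = 0.000308 by limma. Mt1, its neighbour, fell from 376 ± 8.25 to 261 ± 15.2 FPKM, with adjusted p = 0.0226. Scd1, which makes monounsaturated fatty acids, fell as well and had 17.6 ± 0.741 FPKM in the knockout and 29.6 ± 1.53 FPKM in the wild type, with adjusted p = 0.00915. Plin3, a lipid droplet coat protein, had 2.53 ± 0.0559 against 6.24 ± 1.11 FPKM (0.0258). Lcat, the enzyme that esterifies cholesterol on lipoproteins, had 11.5 ± 0.709 against 16.1 ± 0.364 FPKM (0.0448). Cyp4f15, a cytochrome P450 of the fatty acid hydroxylase family, had 3.13 ± 0.772 against 9.43 ± 1.27 FPKM (0.0258). As3mt, which methylates arsenic, fell by 0.82 on the log2 scale, and Npsr1, the receptor of neuropeptide S, fell from 2.79 ± 0.619 to 0.341 ± 0.0631 FPKM, both with adjusted p = 0.0137. Hhatl, Paqr6 and BC026585 also fell, with log2 changes of -0.97, -0.80 and -0.71. Mt2 kept its call in all 18 alternatives. That of Mt1 was lost without knockout replicate 2 (adjusted p = 0.0915) or 3 (0.133) or wild type replicate 2 (0.149, its highest) or 3 (0.112) and with a prior that does not depend on the mean (0.0536), that of Scd1 without knockout replicate 2 (0.0742, its highest) or wild type replicate 2 (0.0565). The other genes named here each lost their call without knockout replicate 2, without knockout replicate 3 and without wild type replicate 2, and, except Npsr1, without wild type replicate 3, with adjusted p up to 0.255 for Lcat. Hhatl and BC026585 lost it without any 1 of the 6 libraries, Plin3 also without knockout replicate 1, and Paqr6 and Lcat also without wild type replicate 1. Over all alternatives Npsr1 kept its call in 13 of 17, Cyp4f15 in 12 of 18, As3mt in 11 of 17, Plin3 and Paqr6 in 10 of 17, Hhatl and BC026585 in 9 of 17 and Lcat in 9 of 18.

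S100b (ENSMUSG00000033208, chromosome 10, 76253853 to 76261159) fell from 49.0 ± 0.830 to 26.6 ± 0.429 FPKM, a log2 fold change of -0.86 (SE 0.04) with adjusted p = 0.000308 by limma, and it kept its call in all 18 alternatives. Its locus overlaps that of Dip2a, so that shared reads cannot be told apart. Gfap (chromosome 11, 102887336 to 102900912), whose locus overlaps the predicted gene Gm26668, rose from 122 ± 1.64 to 265 ± 48.4 FPKM, a log2 fold change of 1.09 (SE 0.12) with adjusted p = 0.0284. Its knockout values were 209, 287 and 298 FPKM. The 23 tested astrocyte markers went both ways, 10 higher and 13 lower. Over all genes 1 rose and 1 fell; adjusted over the list alone 4 rose (Gfap, Apoe, Aqp4 and Clu) and 5 fell (S100b, Slc7a10, Atp1a2, Mlc1 and Aldh1l1). Slc7a10, an amino acid transporter of astrocytes, had 6.80 ± 1.53 against 16.1 ± 3.04 FPKM, and Aqp4, the water channel of astrocyte endfeet, 30.6 ± 3.21 against 22.2 ± 2.14 FPKM. The list did not pass (camera adjusted p = 0.118, and adjusted p = 0.675 with an estimated correlation), while the mixed fry test gave an adjusted p of 1.46e-05. By camera with the preset correlation the unadjusted p was 0.0616 with Gfap and 0.0186 for the other 22 genes without it. These 2 values are not directly comparable, since only the first let the prior depend on the mean. The call of Gfap was lost without knockout replicate 2 (adjusted p = 0.157) or 3 (0.159) or wild type replicate 1 (0.0502), 2 (0.199, its highest) or 3 (0.126), with quantile normalization (0.0756) and with a prior that does not depend on the mean (0.0651), with log2 fold changes from 1.00 to 1.26 over its alternatives.

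The list of 20 tested genes of reactive astrocytes, which includes Gfap, rose against other genes, with 15 members higher (camera adjusted p = 0.0126, but adjusted p = 0.675 with an estimated correlation). Gfap alone passed over all genes, and Gfap and Serpina3n passed adjusted over the list alone. Serpina3n, a secreted protease inhibitor, had 102 ± 6.84 against 78.6 ± 2.63 FPKM. This list's call was lost without knockout replicate 3 (adjusted p = 0.0764), wild type replicate 2 (0.0845) or wild type replicate 3 (0.231, its highest) and with a mean of at least 5 FPKM required (0.0505). Its median log2 fold change of 0.13 became 0.38 without wild type replicate 1 and with both libraries numbered 1 left out.

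The list of microglia markers rose, but not every marker in it did. Of 26 tested members 24 were higher in the knockout, with a median log2 fold change of 0.29 (camera adjusted p = 1.23e-13, but adjusted p = 0.403 with an estimated correlation). Over all genes 1 member rose, Ctss; adjusted over the list alone 15 rose and 0 fell, where 16 had an unadjusted p under 0.05 and all 16 were higher. Ctss, the lysosomal protease cathepsin S, had 40.3 ± 2.62 FPKM in the knockout and 28.5 ± 1.10 FPKM in the wild type (log2 fold change 0.48, SE 0.06, adjusted p = 0.0397 by limma). Hexb, a lysosomal hexosaminidase, had 49.2 ± 1.87 against 37.6 ± 2.18 FPKM, and Csf1r, the receptor microglia need to survive, 22.4 ± 0.425 against 17.9 ± 0.597 FPKM. Aif1 stood at 10.01 ± 0.794 against 10.5 ± 0.724 FPKM, P2ry12 at 11.96 ± 0.463 against 12.3 ± 0.982 FPKM and Tmem119 at 8.18 ± 0.218 against 7.70 ± 0.676 FPKM. Each of these differences was smaller than the wild type SD, though that of Tmem119 was larger than its knockout SD. The list of activated microglia and macrophages rose too, with 11 of 12 members higher (adjusted p = 0.000429, and adjusted p = 0.60 with an estimated correlation). Over all genes 0 of its members passed and 4 had an unadjusted p under 0.05; the same 4 passed adjusted over the list alone. They include Apoe, the main apolipoprotein of the brain, with 2156 ± 32.2 against 1604 ± 121 FPKM, and Ccl6, a chemokine, with 1.84 ± 0.206 against 0.907 ± 0.255 FPKM. The calls of both lists held in all 18 alternatives. The microglia list also passed in 4 of the 9 splits that mix the genotypes, each of which keeps part of any genotype difference. The median of the activated list, 0.33, became 0.22 without wild type replicate 3. The call of Ctss was lost without knockout replicate 2 (adjusted p = 0.243, its highest) or 3 (0.188) or wild type replicate 1 (0.0558), 2 (0.228) or 3 (0.126), with median-of-ratios rescaling (0.0797), quantile normalization (0.0857) or a prior that does not depend on the mean (0.0975), and with both libraries numbered 1 left out (0.0540).

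Genes of myelin and mature oligodendrocytes were higher as a list, but not all of them. Of 35 tested members 28 were higher and 7 lower, with a median log2 fold change of 0.22 and a mean of 0.12 (camera adjusted p = 8.92e-05, but adjusted p = 0.675 with an estimated correlation). Over all genes 1 rose, Qdpr, which regenerates tetrahydrobiopterin, with 108 ± 8.08 against 76.6 ± 2.73 FPKM (adjusted p = 0.0448), and 1 fell, Hapln2, a link protein at nodes of Ranvier, with 4.56 ± 0.801 against 9.83 ± 0.823 FPKM (adjusted p = 0.0284, limma). Adjusted over the list alone 10 rose and 1 fell. Opalin, a membrane protein of oligodendrocytes, had 6.46 ± 1.18 against 3.27 ± 0.456 FPKM. The knockout library numbered 1 stood apart: Plp1, the main myelin protein gene, was at 328 FPKM there and at 497 and 478 FPKM in the other knockout libraries, against 324 to 363 FPKM in the wild type. Mbp had 827 ± 157 against 732 ± 72.8 FPKM, with adjusted p = 0.840. The list's call held in all 18 alternatives, whereas that of Qdpr was lost without knockout replicate 2 (adjusted p = 0.188) or 3 (0.255) or wild type replicate 1 (0.0502), 2 (0.258, its highest) or 3 (0.177), with no filter on low values (0.0589), median-of-ratios rescaling (0.0795), quantile normalization (0.108) or a prior that does not depend on the mean (0.106), and with both libraries numbered 1 left out (0.0529). The call of Hapln2 was lost without knockout replicate 1 (0.0566) or 3 (0.20, its highest) or wild type replicate 1 (0.0506), 2 (0.149) or 3 (0.137), with a prior that does not depend on the mean (0.0536) and with both libraries numbered 1 left out (0.0841).

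**Figure D2:**
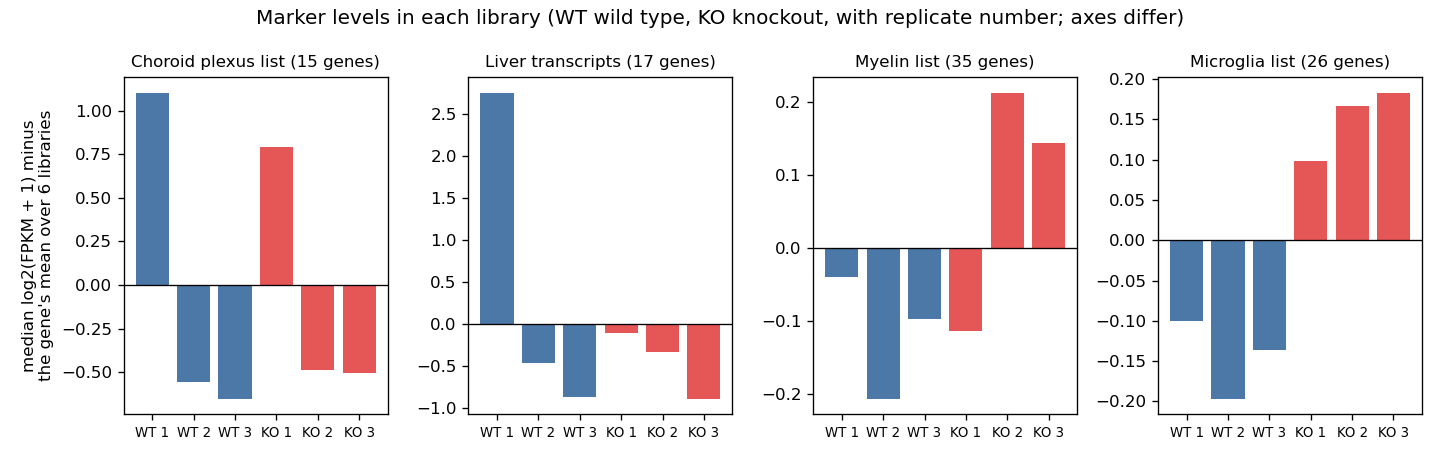
For each of the 6 libraries (horizontal axis), the bar gives the median over a list's genes of log2(FPKM + 1) minus the gene's mean over all libraries (vertical axis, different in each panel). The choroid plexus list is at 1.10 in the first wild type library and 0.79 in the first knockout library, the liver transcripts are at 2.76 in the first wild type library, the myelin list is above 0 in 2 of 3 knockout libraries and the microglia list in 3 of 3.

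Libraries also differed within the groups. Ttr, a transcript abundant in the choroid plexus, was at 990 FPKM in knockout replicate 1 and 1089 FPKM in wild type replicate 1, against 47.1 to 65.6 FPKM in the others, and the choroid plexus list did not differ between genotypes (adjusted p = 0.60 by camera, 0.942 with an estimated correlation). Alb, the albumin gene of liver, was at 339 FPKM in wild type replicate 1 and at 1.31 to 9.85 FPKM elsewhere. With both of these libraries left out, the microglia list kept a median log2 fold change of 0.38 and the myelin list one of 0.35.

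The list of endothelial markers was higher than other genes, with 18 of 20 higher and a median log2 fold change of 0.17 (adjusted p = 0.00178, but adjusted p = 0.675 with an estimated correlation). Over all genes 0 passed, with 3 higher and 1 lower at an unadjusted p under 0.05; adjusted over the list alone Ly6c1 and Cldn5 rose and Mfsd2a, a lipid transporter of the blood-brain barrier, fell, from 20.97 ± 0.774 to 14.0 ± 2.33 FPKM. This list's call was lost without wild type replicate 2 (adjusted p = 0.0605) or wild type replicate 3 (0.0764, its highest). Its median became 0.28 without wild type replicate 1 and with both libraries numbered 1 left out. Neuronal lists did not pass: excitatory neurons had adjusted p = 0.118 by camera, inhibitory neurons 0.194 and synaptic genes 0.176, with 0 members past the threshold over all genes or adjusted over the list alone by limma and 0, 1 and 0 at an unadjusted p under 0.05. Dcx, a marker of immature neurons, was at 2.53 ± 0.215 against 2.86 ± 0.338 FPKM.

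**Figure D3:**
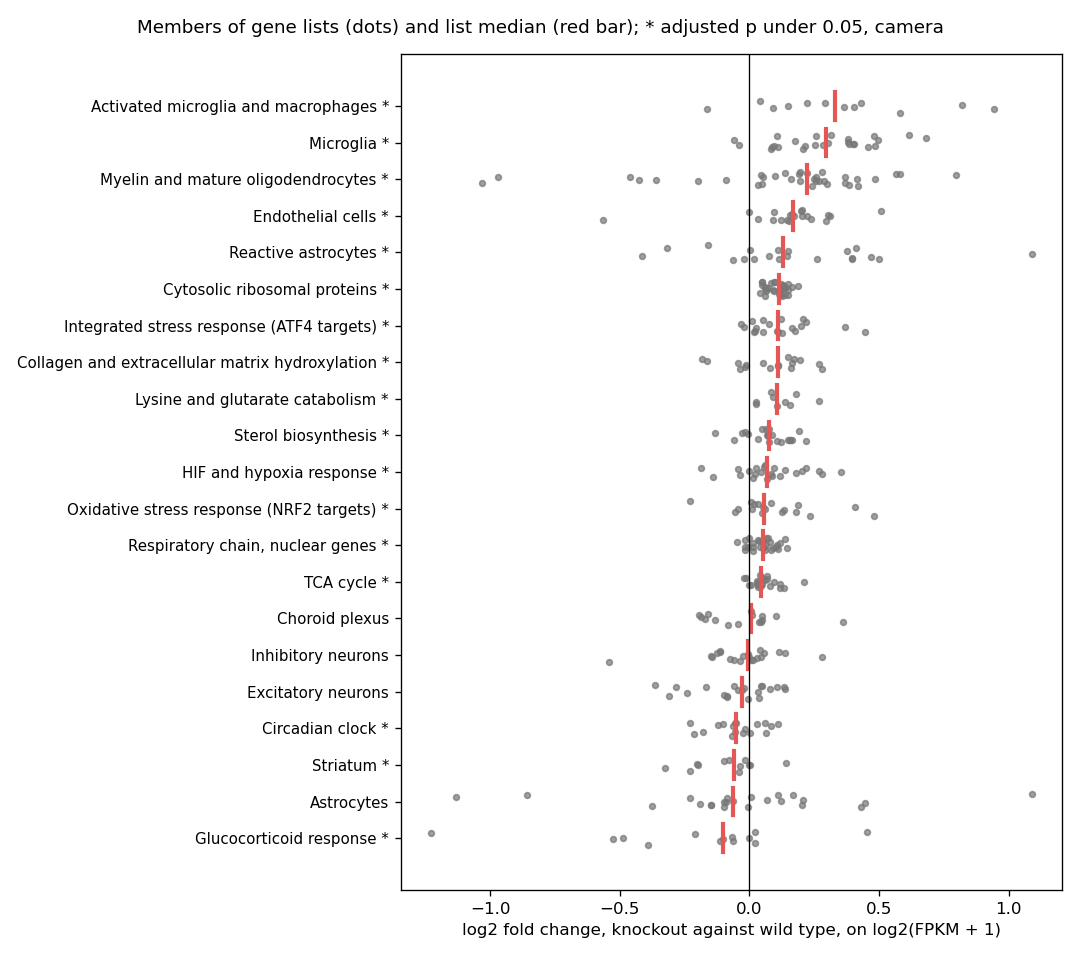
Log2 fold change on log2(FPKM + 1), knockout against wild type (horizontal axis), of the tested members (dots) of 21 gene lists (rows), with the list median as a red bar; an asterisk marks an adjusted p under 0.05 by camera with the preset correlation. Microglia members sit mostly right of 0, with a median of 0.29, and astrocyte members on both sides, with a median of -0.06.

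Of 25 tested genes that handle 2-hydroxyglutarate and 2-oxoglutarate, 16 were higher and 9 lower, and L2hgdh was the only lower one with an unadjusted p under 0.05. L2hgdh alone passed over all genes; adjusted over the list alone 3 rose (Glud1, Adhfe1 and Idh2) and L2hgdh fell. Glud1, glutamate dehydrogenase, had 116 ± 0.860 against 98.5 ± 2.59 FPKM, Adhfe1, the hydroxyacid-oxoacid transhydrogenase, 8.98 ± 0.724 against 6.42 ± 0.409 FPKM, and Idh2, the mitochondrial isocitrate dehydrogenase, 29.3 ± 0.449 against 26.0 ± 0.538 FPKM. D2hgdh, the enzyme for the other enantiomer, was at 4.96 ± 0.879 against 4.22 ± 0.690 FPKM (adjusted p = 0.795), and Idh1 at 19.8 ± 1.63 against 17.1 ± 1.41 FPKM (0.552). The list did not pass (camera adjusted p = 0.115, and adjusted p = 0.675 with an estimated correlation). By camera with the preset correlation the unadjusted p was 0.0546 with L2hgdh and 0.0131 for the other 24 genes without it, whose directional fry p was 0.0555. The 2 camera values are not directly comparable, since only the first let the prior depend on the mean. The mixed fry test gave an adjusted p of 1.43e-05 with L2hgdh and an unadjusted p of 2.77e-05 without it. The 9 tested genes of lysine and glutarate catabolism were all higher, with a median log2 fold change of 0.11 (adjusted p = 0.0254, but adjusted p = 0.60 with an estimated correlation), with 0 past the threshold over all genes, 1 at an unadjusted p under 0.05 and that gene, Etfa, past it adjusted over the list alone. This call was lost without knockout replicate 1 (adjusted p = 0.0604) or wild type replicate 3 (0.231, its highest), with no filter on low values (0.0812) and with a mean of at least 5 FPKM required (0.0769). The median became 0.17 without wild type replicate 1.

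Mitochondrial lists moved little. The 22 tested TCA cycle genes, 19 of them higher, had a median log2 fold change of 0.05 (adjusted p = 0.0126, but adjusted p = 0.675 with an estimated correlation), and the 29 nuclear genes of the respiratory chain, 23 of them higher, one of 0.05 (adjusted p = 0.0126, but adjusted p = 0.710 with an estimated correlation). In neither list did a member pass over all genes or adjusted over the list alone by limma, and 2 and 3 members had an unadjusted p under 0.05. Dlat was at 45.2 ± 1.86 against 41.1 ± 0.534 FPKM and Ndufs1 at 59.0 ± 1.78 against 53.2 ± 1.86 FPKM. The TCA call was lost without knockout replicate 1 (adjusted p = 0.179) or wild type replicate 3 (0.143), that of the respiratory chain without knockout replicate 1 (0.684) or wild type replicate 1 (0.0581), and both with quantile normalization (0.136 and 0.307), with sample weights (0.169 and 0.207) or with both libraries numbered 1 left out (0.210 and 0.812, the highest for each). The fold changes shrank as well: the TCA median became 0.03 and that of the respiratory chain 0.01 without knockout replicate 1, and 0.03 and 0.02 with both libraries numbered 1 left out. With quantile normalization they were 0.0192 and 0.0108.

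Enzymes that use 2-oxoglutarate, and pathways they control, were examined as lists. The 22 tested histone lysine demethylases and TET enzymes went 11 each way (adjusted p = 0.468, and adjusted p = 0.760 with an estimated correlation). By limma 0 passed over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05. Kdm3a was at 8.17 ± 0.285 against 7.33 ± 0.242 FPKM and Tet2 at 3.64 ± 0.219 against 4.16 ± 0.169 FPKM. The list of the HIF and hypoxia response was slightly higher than other genes, with 18 of 23 higher and a median of 0.07 (adjusted p = 0.0126, but adjusted p = 0.428 with an estimated correlation). None of the 23 passed over all genes and 5 had an unadjusted p under 0.05; adjusted over the list alone P4ha1, a collagen prolyl hydroxylase subunit, and Vegfa, the angiogenic growth factor, rose, the latter with 45.6 ± 3.26 against 35.5 ± 3.20 FPKM. The call was lost without knockout replicate 3 (adjusted p = 0.0636, its highest). Genes of collagen and matrix hydroxylation also passed, with 11 of 17 higher and a median of 0.11 (adjusted p = 0.0407, but adjusted p = 0.60 with an estimated correlation), 0 past over all genes, 4 at an unadjusted p under 0.05 and 2, P4ha1 and Col4a2, adjusted over the list alone. That call was lost without any 1 of the knockout libraries (adjusted p from 0.0604 to 0.0773), without wild type replicate 3 (0.563, its highest) or with a replicate block (0.0507). The median became 0.06 without knockout replicate 1, 0.17 without wild type replicate 1 and 0.03 without wild type replicate 3.

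Ribosomal protein genes were higher as a list, by a small amount. All 33 tested members had positive fold changes, with a median of 0.11 (camera adjusted p = 5.82e-10, but adjusted p = 0.60 with an estimated correlation). By limma 0 passed over all genes or adjusted over the list alone, and 13 had an unadjusted p under 0.05. Rps23 was at 236 ± 7.66 against 213 ± 4.69 FPKM. These genes have many processed pseudogenes that can share reads. The median became 0.07 without knockout replicate 1 and 0.06 with quantile normalization.

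Stress lists moved in small steps. The list of ATF4 targets of the integrated stress response was higher than other genes, with 18 of 20 higher and a median log2 fold change of 0.11, which became 0.16 without wild type replicate 1 (adjusted p = 0.00178, but adjusted p = 0.403 with an estimated correlation), 0 past over all genes, 4 at an unadjusted p under 0.05 and 1, the transcription factor Atf5, adjusted over the list alone (11.8 ± 0.405 against 8.43 ± 0.776 FPKM). The list of NRF2 targets of the oxidative stress response was higher too, with 15 of 18 higher and a median of 0.06 (adjusted p = 0.0163, but adjusted p = 0.60 with an estimated correlation), 0 past over all genes, 5 at an unadjusted p under 0.05 and 1, the haem oxygenase Hmox1, adjusted over the list alone (3.69 ± 0.136 against 2.37 ± 0.329 FPKM). So was the sterol biosynthesis list, with 17 of 22 higher (adjusted p = 0.0188, but adjusted p = 0.675 with an estimated correlation), and by limma 0 passed over all genes or adjusted over the list alone while 2, Hmgcs1 and Fdps, had an unadjusted p under 0.05. The NRF2 call was lost without knockout replicate 3 (adjusted p = 0.0726), wild type replicate 2 (0.0845) or wild type replicate 3 (0.0764) and with quantile normalization (0.187, its highest). Its median became 0.12 without wild type replicate 1, 0.13 with both libraries numbered 1 left out and 0.02 with quantile normalization. The sterol call was lost without knockout replicate 1 (0.179) or 3 (0.0773) or wild type replicate 2 (0.0739) or 3 (0.143) and with a mean of at least 5 FPKM required (0.0531) or sample weights (0.208, its highest).

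The glucocorticoid response list fell, with 10 of 13 members lower and a median log2 fold change of -0.10 (adjusted p = 2.02e-05, but adjusted p = 0.60 with an estimated correlation). Mt1 and Mt2, which respond to metals as well as to glucocorticoids, fell over all genes; adjusted over the list alone Tsc22d3, the glucocorticoid-induced leucine zipper, fell with them, from 33.8 ± 1.31 to 23.9 ± 2.69 FPKM. Fkbp5, another such target, was at 23.3 ± 1.89 against 24.4 ± 0.867 FPKM. At an unadjusted p under 0.05 there were 3 lower members and 1 higher, the cell cycle inhibitor Cdkn1a, at 7.82 ± 2.20 against 5.30 ± 0.278 FPKM. The list of circadian clock genes was lower than other genes, with 12 of 18 lower and a median of -0.05 (adjusted p = 0.0239, but adjusted p = 0.60 with an estimated correlation), and so was that of striatal markers, with 10 of 12 lower and a median of -0.06 (adjusted p = 0.0264, but adjusted p = 0.60 with an estimated correlation). In each of the last 2 lists 0 members passed over all genes or adjusted over the list alone by limma and 1 had an unadjusted p under 0.05, Nr1d2 among the clock genes and Ppp1r1b among the striatal ones. The median of the glucocorticoid list became -0.05 without knockout replicate 1 and -0.16 without knockout replicate 3. The clock call was lost without knockout replicate 2 (adjusted p = 0.0626) or 3 (0.0773) or wild type replicate 3 (0.231, its highest) and with no filter on low values (0.0521), its median becoming -0.03 without knockout replicate 2. The striatal call was lost without knockout replicate 1 (0.0616) or 3 (0.0726) or wild type replicate 1 (0.0681) or 3 (0.143, its highest), with sample weights (0.101) and with both libraries numbered 1 left out (0.0982). Its median ranged from -0.12 without wild type replicate 3 to -0.01 without wild type replicate 1.

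Sos2 (ENSMUSG00000034801, chromosome 12, 69583762 to 69681852, minus strand), a guanine nucleotide exchange factor for Ras, lies beside L2hgdh on the same strand, with 8583 bp between them. It rose from 8.51 ± 0.353 to 14.0 ± 0.612 FPKM, a log2 fold change of 0.66 (SE 0.06) with adjusted p = 0.0137 by limma. Of 19 tested genes in the list around L2hgdh it alone passed, over all genes and adjusted over the list alone, and the list did not (camera adjusted p = 0.284, and adjusted p = 0.675 with an estimated correlation). Other genes that rose were Col16a1, a collagen, with 13.8 ± 0.632 against 8.29 ± 0.861 FPKM (adjusted p = 0.0284), Rhobtb3, a Rho-related protein (log2 fold change 0.54, 0.0465), Abhd3, a phospholipase (0.42, 0.0258), and S100a13, a calcium-binding protein (0.41, 0.0259). Tubb4a, a tubulin gene of oligodendrocytes, and Scrg1 had the next smallest p among higher genes with groups that did not overlap and did not pass, at 0.0545 and 0.0573. The call of Sos2 was lost without knockout replicate 2 (adjusted p = 0.0916) or 3 (0.110, its highest) or wild type replicate 2 (0.0565) or 3 (0.0694) and with both libraries numbered 1 left out (0.0540). The calls of Col16a1, Rhobtb3, Abhd3 and S100a13 were lost without any 1 of these same libraries, with adjusted p up to 0.199, 0.257, 0.191 and 0.191. That of Rhobtb3 was lost without any 1 of the 6 libraries and with no filter on low values (0.0737), those of Col16a1 (0.0846) and Abhd3 (0.0566) also without knockout replicate 1, and that of S100a13 (0.0506) also without wild type replicate 1. All 4 were also lost with a prior that does not depend on the mean and with both libraries numbered 1 left out. Median-of-ratios rescaling ended those of Rhobtb3 (0.0795) and S100a13 (0.0528), and quantile normalization that of Rhobtb3 (0.0857).

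Among predicted genes, named after their values were seen, 2 passed. Gm21984, a processed transcript on chromosome 7 (126942144 to 126952873) that overlaps Kctd13, Asphd1 and Sez6l2, fell from 11.9 ± 0.977 to 1.30 ± 0.678 FPKM (adjusted p = 0.00915 by limma), and its reads cannot be told apart from those of the overlapping genes. Its call was lost without wild type replicate 2 or 3 and with both libraries numbered 1 left out, with adjusted p up to 0.0567. Gm21961 (chromosome 15, 64979544 to 65014904) was at 3931, 1987 and 1824 FPKM in the knockout and listed at 0 in each wild type library. Its annotated transcript is 114 nt long, and the value in the first knockout library equals that of the 5S RNA gene n-R5s202, also 114 nt, in the same library. That gene was at 4053 and 4100 FPKM in wild type replicates 1 and 3 and listed at 0 in the other 3 libraries. Gm21961 counts among the 24 genes and the 9 higher ones, although its value is as unreliable as those of the short RNAs left out.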

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

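Tests with both libraries numbered 1 left out were chosen after the data were seen. The main counts were 24 genes (9 higher, 15 lower) and 17 lists. A replicate block gave 5 genes (1 higher, 4 lower) and an adjusted p of 0.0563 for L2hgdh at the same log2 fold change of -0.91. No protocol states that the numbers pair the samples. Deviations of same-numbered libraries correlated at 0.301, 0.111 and -0.0641. Knockout replicate 3 correlated better with wild type replicate 2 (0.378) than with its own number. Deviations from a mean of 3 libraries depend on each other, so these values cannot decide whether the numbers pair the samples. The libraries numbered 1 were both rich in choroid plexus transcripts. Sample weights gave 67 genes (39 higher, 28 lower), no mean-dependent prior 13 (2 higher), and rescaling by median-of-ratios or quantiles 5 higher each. Leaving out both libraries numbered 1 gave 13 genes (6 lower), with L2hgdh at -0.98. The cause was not tested, except that a block and fewer samples leave fewer residual degrees of freedom. With 1 library left out, genes ranged from 3 to 29 (1 to 19 higher, 2 to 13 lower), lists from 8 to 20 and L2hgdh from -0.98 to -0.86. Of the 24 genes, 3 kept their call in every alternative (Mt2, S100b and Gm21961) and 0 changed direction. The value of Gm21961 is unreliable, as its annotated transcript is 114 nt long and its level in knockout replicate 1 equals that of a 5S RNA gene. Of the 17 lists, 6 kept theirs in all 18 alternatives; 46 of 752 list results lost the threshold and 32 gained it. Of 3236 results for named genes, 144 lost it and 22 gained it. L2hgdh, below 5 FPKM, had no value under the stricter filter. DESeq2 and a count filter were not run, as the files hold no counts. Depth limits genes near 1 FPKM most.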

Other observations

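The test on length and GC content was written before its value was seen. The tests on time of day, neuronal share, metallothioneins, genes near L2hgdh, reads assigned to Sos2, read-through, the splits of the samples and the libraries with choroid plexus transcripts, and the look at called genes that lie close together, were chosen or worded after the results they measure had been seen.

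Among lists not described above, heat shock proteins had 18 of 19 members higher with a median log2 fold change of 0.05, just short of the threshold (camera adjusted p = 0.0863), and histone and DNA methyltransferases 13 of 18 lower with a median of -0.02 (0.0863). Oligodendrocyte precursors had a median of 0.08 (0.152) and ependymal genes of 0.19 (0.202). Interferon response genes (0.957), immediate early genes (0.629), p53 targets (0.468), glycolysis (0.427), pericytes and fibroblasts (0.804), blood cells (0.302), immature neurons (0.612) and mitochondrially encoded genes (0.983) did not pass, and neither did cortex and hippocampus (0.351), cerebellum (0.207), thalamus (0.468), hypothalamus (0.351) or olfactory bulb (0.612). With an estimated correlation the adjusted p was 0.60 or more in each of these lists.

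The libraries also differed in transcripts of the choroid plexus and liver, whose source was not tested. In wild type replicate 1 the 17 liver transcripts measured, a list written after the values were seen, had a median of 15.2 FPKM against 0.15 to 0.864 FPKM in the other libraries, led by Alb at 339 FPKM and Apoa2 at 77.9 FPKM. The choroid plexus list had a median of 5.44 FPKM in knockout replicate 1 and 7.22 FPKM in wild type replicate 1 against 0.988 to 1.14 FPKM elsewhere. Selenof was at 18824 FPKM in knockout replicate 1 and at 110 to 127 FPKM in the others.

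For the rise of the microglia list, a carry-over of choroid plexus and liver RNA is argued against, since without the first library of each group the median rose to 0.38. A lower share of neurons would raise the markers of every other cell type alike. The microglia median lay 0.358 above that of astrocytes (permutation p over genes 7e-05). This p treats genes as independent and is too small, since the estimated correlations within the 2 lists were 0.146 and 0.147. The size of the gap, rather than this p, goes against a lower share of neurons as the whole cause. Astrocyte markers went both ways and the myelin (0.22) and endothelial (0.17) medians were also above 0, so a part is not excluded. A smooth trend with transcript length and GC content was small (SD 0.0162 log2 over tested genes), and removing it left 0.276. The real split of the 6 samples gave the highest median (0.293), 1 of 10 splits, with 0.170 as the highest other, medians being taken without sign. With 10 splits a share under 0.05 cannot be reached, so this does not decide. The list also passed by camera in 4 of the 9 other splits (adjusted p down to 2.84e-06). Each of these keeps part of any genotype difference, so passing there tells neither for nor against one. A change in microglial RNA stays open as a hypothesis that no test here decides, and the members moved unevenly, from -0.06 for Aif1 and -0.04 for P2ry12 to 0.62 for Tyrobp and 0.68 for Cd68 on the log2 scale.

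The fall of the glucocorticoid response list is led by Mt1 and Mt2. Without them the remaining 11 genes, 8 of them lower, had p = 0.0101 by camera with the preset correlation and a prior that does not depend on the mean. By fry, a bound added after the camera value was seen, p was 0.331, so whether the metallothioneins alone carry it cannot be told apart. Choroid plexus and liver RNA is argued against by an adjusted p of 0.00230 without the first libraries. Brains taken at another time of the day may contribute: 8 genes that peak with Per and Dbp had a mean log2 fold change below that of 5 genes in the opposite phase with Arntl (difference -0.14, exact two-sided permutation p over genes 0.00311, genes not being independent), and sets altered after the members were seen, with Hlf added and Cry1 left out, gave p = 0.0112 by the same exact permutation test. No collection times are in the labels, and an effect of the genotype on the clock or on steroid signalling stays open as well.

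Sos2 was higher right beside the disrupted gene. Whether L2hgdh reads were misassigned to Sos2 depends on the transcript lengths assumed. With the longest annotated transcript of each gene, Sos2 gained 30.7 fragments per M (mega) fragments. That is 14.0 (SE 2.40) more than all L2hgdh fragments of the wild type. On these lengths the value argues against misassigned reads, but the SE leaves out the choice of transcript. Read-through from L2hgdh, which lies upstream on the same strand, cannot be told apart from other causes, since the gain of 5.47 FPKM, above the 2.81 FPKM lost by L2hgdh, exceeded the wild type level of L2hgdh by 0.476 FPKM with an SE of 0.463. A donor-strain segment kept with the allele is also possible: 3 of 52 other genes within 5 Mb (5.77%) had an unadjusted p under 0.05 against 8.58% elsewhere, with an exact upper limit of 15.9%, which does not exclude an effect on 1 neighbour. A regulatory effect of the knockout on Sos2 was not tested apart from these.

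Some genes past the threshold lay within 5 Mb of each other. There were 6 such pairs among the 24 genes, against a mean of 1.53 in 10000 random draws of as many tested genes. A share of 0.0093 of the draws had at least 6. The cause was not tested. Besides Mt1 with Mt2 and L2hgdh with Sos2 the pairs were Scd1 with As3mt on chromosome 19 and Hapln2, Paqr6 and S100a13 with each other on chromosome 3.

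Of the 10 splits of the 6 samples into 3 and 3, 1, the real one, gave 24 genes, and the highest of the others gave 2. For lists the real split gave 17 and the 9 others 4 to 18, with a median of 12 and 2 of 10 splits at 17 or more. Many lists thus passed by camera with the preset correlation when the genotypes were mixed as well. Each mixed split keeps part of any genotype difference, so these counts do not show how often lists pass without one. The split with 18 set knockout replicate 1 with wild type replicates 2 and 3. With 10 splits the share cannot go under 0.05 for either count.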
